A study of Homo sapiens with 2 samples.

How the data were processed

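Polyadenylated RNA was sequenced from KG1a cells, an established human acute myeloid leukemia line with an immature, CD34-positive surface phenotype. The cells had been gated as CD34-positive and CD38-negative and separated by flow cytometry into a fraction with a high surface level of ESAM (ESAM-Hi) and a fraction without it (ESAM-Neg). ESAM is an adhesion protein of endothelial cells, platelets and hematopoietic stem cells. There was 1 library per group, 2 libraries in all. RNA was extracted with the RNeasy Mini kit and libraries were made with the TruSeq stranded mRNA kit. Each library's group was taken from its label. The value column of the ESAM-Neg library is headed "Lo", which was not used for the grouping.

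The deposited values are FPKM, fragment numbers scaled to transcript length and sequencing depth, with 1 value per gene symbol and library. The submitters' processing notes name TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19, Cuffnorm 2.2.1 and the human build hg19. The gene annotation, the strand setting and the scaling option of Cuffnorm are not stated, so how the 2 libraries were scaled to each other is unknown. The values are not counts and no count model was fitted. Both files list the same 23284 symbols in the same order, each once, so no values had to be combined.

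FPKM hide the sequencing depth, but their low values keep a trace of it. Among 1631 genes above 0 in both libraries and below 0.3 FPKM in ESAM-Hi, 67.0% had a ratio between the libraries equal to a ratio of whole numbers up to 10 times a common step (tolerance 0.0001), against 0.121% on average for 50 shifted steps. The step puts the depth of ESAM-Hi at 1.18 times that of ESAM-Neg, provided that the values were scaled by library totals alone. With transcript lengths from GENCODE release 29, 138 genes of at least 1000 bases place 1 FPKM at about 11.4 fragments per kilobase in ESAM-Hi and 9.72 in ESAM-Neg. Intervals given for single genes are 95% exact (Clopper-Pearson) binomial intervals of such approximate fragment numbers. They cover counting error only and rest on a median transcript length that is not the authors' own.

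Ratios are log2((ESAM-Hi + 1)/(ESAM-Neg + 1)) of the FPKM as deposited, and all log2 ratios are on this scale, which understates differences of low genes. A gene counted as expressed with at least 1 FPKM in at least 1 library. By a fixed rule of size it counted as higher in ESAM-Hi at a log2 ratio of at least 1 and as lower at -1 or less. With 1 library per group there is no replicate error, so no p-value or standard error was computed and the rule is not a test. Exact zeros are given as "listed at 0", with no fold.

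The design, 42 gene lists, the size rule and the rule for named genes were fixed before the data were examined. A list with at least 5 expressed members was described by the median log2 ratio of those members and by the percentile of that median among 10000 random lists of as many expressed genes, matched in 20 bins of mean expression. A list was said to stand apart where its median lay outside the central 95% of the random lists. Percentiles describe these 2 libraries, not the conditions, and genes of a list are not independent. The lists hold 930 different genes found in the files, 73 of them in more than 1 list.

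Named genes were ESAM, CD34 and CD38; among genes of at least 5 FPKM, the 12 with the highest and the 12 with the lowest ratio, passing over symbols of unnamed loci, microRNAs, small nucleolar and small nuclear RNAs, antisense RNAs and pseudogenes (36 and 34 of them); the 3 leading members of each list that stood apart; every member of the 2 TGFβ lists past the size rule; up to 2 members of each list past the rule in each direction; and a fixed set of TGFβ genes, among them TGFB1, TGFBR1, TGFBR2, SMAD2, SMAD3, SMAD4 and SMAD7. Where genes outside this rule are named, the text says how they were chosen, apart from the first and last genes of chromosome stretches and FGFR1, for which a list is named. Not every gene that the rule selects is printed.

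Gene order along the chromosomes was taken from an annotation of build GRCh38. Since the authors used hg19, only the order is used and no coordinates are given. Of 9062 genes with at least 5 FPKM that were not short RNA genes, 8897 were placed. Their ratios were centred on the median, capped at 1 in size, and the highest-scoring stretch of neighbours on each chromosome and in each direction was found after subtracting 0.2 per gene. Scores were compared with 1000 shuffled gene orders. This search was devised after neighbouring genes had been noticed among those past the size rule.

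Alternatives were other pseudocounts, other scalings between the libraries, other filters on low values, other fold limits, other ways of matching random lists, and the list mean in place of the median. Alternatives added after seeing the data left out short RNA genes, the sort markers, single list members or the genes of 2 chromosome stretches, or matched random lists on transcript length. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. On simulated data with counting error alone and equal depth, the size rule passed 0.0697% of unchanged genes. It recovered 99% of genes set 4-fold apart, all with a mean of at least 5 FPKM, so genes below that level were not covered. Of 100 random lists drawn from the data, 4 fell outside the central 95%. XIST and Y-linked genes were not analysed here.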

Results

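RNA was sequenced from CD34-positive, CD38-negative KG1a cells immediately after sorting into an ESAM-Hi and an ESAM-Neg fraction, with 1 library each. Of 23284 listed genes, 11518 reached 1 FPKM in at least 1 library, and 7746 were listed at 0 in both. In ESAM-Hi 14924 genes were above 0 and in ESAM-Neg 14553. The ESAM-Hi library was an estimated 1.18 times as deep, if the values were scaled by library totals alone. The FPKM summed to 558040 in ESAM-Hi and 612651 in ESAM-Neg, of which short RNA genes (microRNA, small nucleolar, small Cajal body, small nuclear and vault RNA genes) took 13.9% and 16.1%. None of the values has a replicate, so the spread between cultures or sorts is unknown for all of them.

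ESAM differed in the direction of the labels. It was at 144 FPKM in ESAM-Hi and 9.17 FPKM in ESAM-Neg, a log2 ratio of 3.83, with a counting interval of 11.8-fold to 21.0-fold. CD34, the progenitor antigen by which both fractions were gated, was also higher in ESAM-Hi, at 331 against 161 FPKM (log2 ratio 1.03). CD38 was listed at 0 in both libraries. ESAM lies in a stretch of chromosome 11 whose genes were higher in ESAM-Hi by a median of 1.25-fold, given in full further on.

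Across the expressed genes the fractions had a Pearson r of 0.910 on the log2 scale and a Spearman rho of 0.940. Among genes of at least 5 FPKM the Pearson r was 0.855. Without replicates there is no r between libraries of the same fraction to set these against. These are correlations across genes, which are not independent replicates. The median log2 ratio was -0.01, its quartiles were -0.23 and 0.20 and its SD was 0.81. By the size rule 322 genes were higher in ESAM-Hi and 288 were lower, together 5.30% of the expressed genes. The counts depended on how low values were weighted: a pseudocount of 5 gave 144 higher and 152 lower genes. They depended on the scaling between the libraries as well, with 372 higher and 239 lower after equal scaling of the sums and 340 and 260 after equal scaling of the 75th percentiles. Without the 167 expressed short RNA genes they were 275 and 236.

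**Figure D1:**
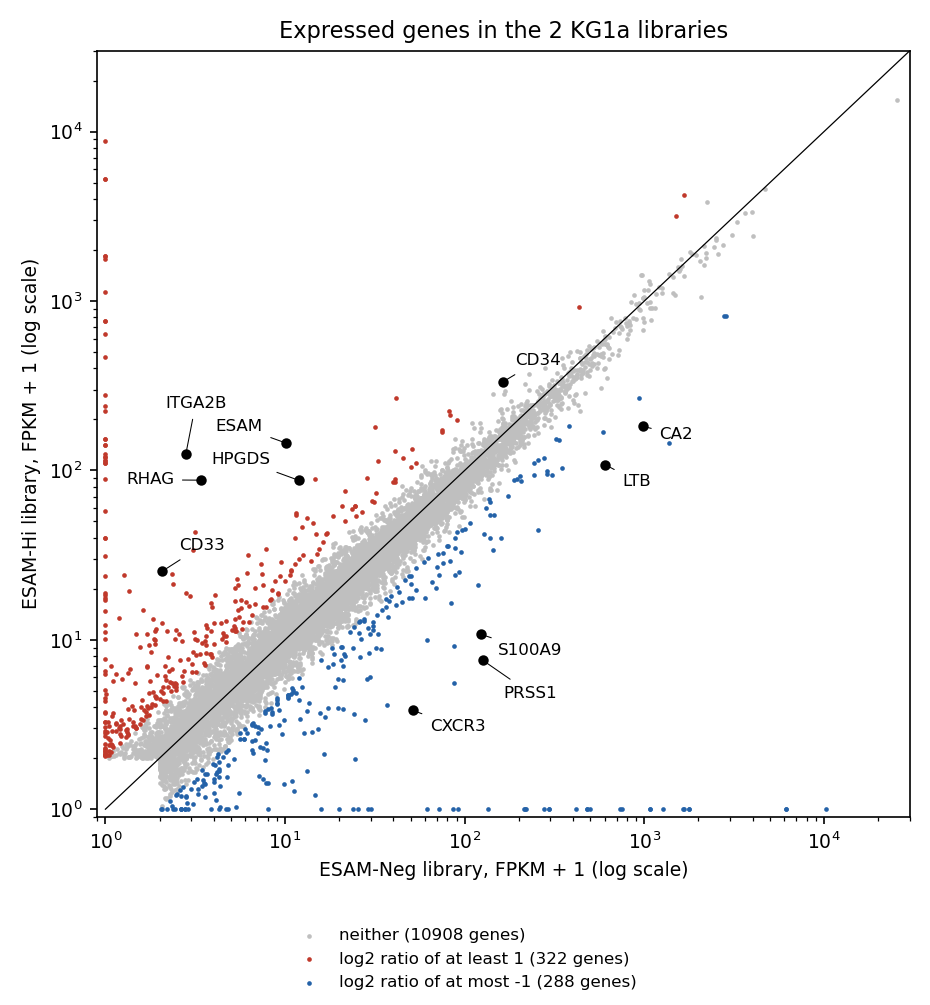
Each point is 1 of the 11518 expressed genes, with FPKM + 1 in ESAM-Neg on the horizontal and in ESAM-Hi on the vertical log axis and the line of equal values drawn. The 322 genes with a log2 ratio of at least 1 are red, the 288 at -1 or less are blue and the others are grey. Names mark 11 genes, such as ITGA2B far above the line and CXCR3 far below it. Points along the horizontal axis are at or near 0 in ESAM-Hi, and those along the vertical axis are at or near 0 in ESAM-Neg.

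Among genes of at least 5 FPKM, with 36 symbols of unnamed loci and small RNAs or the like passed over, the gene furthest toward ESAM-Hi was ITGA2B, the αIIb chain of the fibrinogen receptor of megakaryocytes and platelets, at 124 FPKM against 1.80 (log2 ratio 5.48, counting interval 51.4-fold to 93.9-fold). RHAG, a membrane glycoprotein of the erythroid Rh complex, was at 86.5 against 2.40 FPKM (4.68), and IL1RL1, the receptor of interleukin 33, at 23.1 against 0.262 FPKM (4.26). CD33, a sialic acid-binding receptor of myeloid cells, was at 24.4 against 1.07 FPKM (3.62), and ZBTB16, which encodes the transcription factor PLZF, at 32.9 against 2.05 FPKM (3.47). SLC5A12, a sodium-coupled lactate transporter, and CHRM3, a muscarinic acetylcholine receptor, had log2 ratios of 3.84 and 3.50. CRISP3, a secreted cysteine-rich protein, was at 23.5 against 1.36 FPKM (3.38), and its relative CRISP2 at 10.1 FPKM was listed at 0 in ESAM-Neg. SCARNA1, a small Cajal body RNA, was at 13.8 FPKM and listed at 0 in ESAM-Neg. RPS28, a ribosomal protein gene with a short main transcript, had a log2 ratio of 3.78.

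Toward ESAM-Neg 34 such symbols were passed over, and furthest among the other genes of at least 5 FPKM that were above 0 in both libraries was PRSS1, which encodes cationic trypsinogen, at 6.57 FPKM in ESAM-Hi and 125 FPKM in ESAM-Neg (log2 ratio -4.06). Its relatives TRY6 and PRSS3 had log2 ratios of -3.97 and -3.14, and reads shared among these similar genes cannot be separated in FPKM. CXCR3, a chemokine receptor of activated lymphocytes, was at 2.82 against 50.6 FPKM (-3.75). KLRC1, an inhibitory receptor of natural killer (NK) cells, was at 0.206 against 13.6 FPKM (-3.60), and ZNF683, a transcription factor of tissue-resident lymphocytes, at 3.11 against 35.7 FPKM (-3.16). S100A9, a calcium-binding protein of myeloid cells, was at 9.76 against 123 FPKM (-3.52), and the imprinted non-coding RNA H19 at 8.19 against 86.0 FPKM (-3.24). SAMD3 and EMP1, an epithelial membrane protein, had log2 ratios of -3.05 and -2.99. FXYD2, a regulator of the sodium pump, was at 14.8 FPKM in ESAM-Neg and SCARNA21 at 18.9 FPKM, and both were listed at 0 in ESAM-Hi.

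The title of the series concerns autonomous TGFβ signalling, so the genes of that pathway were compared between the fractions. The ligand TGFB1 was at nearly the same level in both, 111 FPKM in ESAM-Hi and 106 FPKM in ESAM-Neg (log2 ratio 0.07), and its counting interval, 0.987-fold to 1.12-fold, included equality. Its receptors TGFBR1 and TGFBR2 had log2 ratios of 0.40 (interval 0.958-fold to 1.89-fold) and 0.22 (1.06-fold to 1.299-fold). Among the SMAD proteins that carry the signal to the nucleus, SMAD3 was at 29.2 against 17.0 FPKM (0.74, interval 1.36-fold to 2.16-fold), SMAD2 at 13.7 against 11.2 FPKM (0.26, 0.986-fold to 1.51-fold) and SMAD4 at 9.96 against 8.68 FPKM (0.18, 0.825-fold to 1.60-fold). The intervals of TGFBR1, SMAD2 and SMAD4 included equality. They rest on assumed lengths of 680, 1378 and 779 bases, against 4613 bases for TGFBR2. A shorter assumed length gives fewer fragments and a wider interval, so which intervals included equality cannot be compared between these genes. Of 22 expressed pathway components, 18 were above 0 and 4 below, and none was past the size rule. Their median of 0.20 lay at percentile 96.9, inside the central 95% of the random lists, but outside with a pseudocount of 5 (98.0) and among unmatched lists (99.6).

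TGFβ target genes were on balance lower in ESAM-Hi. Of 25 expressed targets, 1 was higher by the size rule, 4 were lower and 20 were neither. ID1, an inhibitor of helix-loop-helix factors, was higher, at 21.9 against 4.43 FPKM (2.08). Lower were CDKN1A, the cell cycle inhibitor p21, at 2.95 against 16.2 FPKM (-2.12), JUNB, a subunit of the AP-1 transcription factor, at 24.2 against 92.1 FPKM (-1.88), ID2, a relative of ID1, at 21.0 against 64.5 FPKM (-1.58), and BHLHE40, a transcriptional repressor, at 16.6 against 49.6 FPKM (-1.52). SMAD7, the feedback inhibitor of the pathway, was at 2.65 against 4.19 FPKM (-0.51), with an interval of 0.408-fold to 1.01-fold. The targets' median of -0.40 was below those of all 10000 random lists, although 12 of the 25 were above 0 and leaving out 1 member moved it to as little as -0.13. The call ended without a filter on low values (percentile 6.87) and with the list mean (2.55).

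Genes of the megakaryocyte and platelet lineage formed the list furthest toward ESAM-Hi. Of 9 expressed members 5 were higher and none lower by the size rule, and their median of 1.12 exceeded those of all random lists. Beside ITGA2B these were its partner chain ITGB3 at 17.9 against 1.81 FPKM (2.75), the lineage transcription factor GATA1 at 2.27 FPKM and listed at 0 in ESAM-Neg, and, both named after their values were seen, NFE2 at 27.8 against 8.49 FPKM (1.60), a transcription factor of platelet formation, and RAB27B at 52.8 against 23.7 FPKM (1.12), a regulator of platelet granule release. The abundant platelet chemokine genes PF4 and PPBP, looked up after the list's result was seen, were listed at 0 in both libraries.

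Endothelial genes, the lineage for which ESAM was named, also stood apart toward ESAM-Hi, with a median of 0.62 at percentile 100. Of 11 expressed members 3 were higher, namely ESAM, the secreted angiogenic factor EGFL7 at 132 against 49.8 FPKM (1.39) and the transcription factor ERG at 17.7 against 8.17 FPKM (1.03). PECAM1, an adhesion molecule of the same cells, was lower, at 0.961 against 6.71 FPKM (-1.97). Without ESAM the median was 0.54, still at percentile 100. The list holds 28 genes, and CDH5, TEK, SOX17, SOX18 and CLEC14A, named after their values were seen, were listed at 0 in both libraries.

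Hematopoietic stem cell genes and leukemia surface antigens lay toward ESAM-Hi as well. Of 26 expressed stem cell genes, 8 were higher and 2 lower, with a median of 0.32 at percentile 100. SPINK2, a protease inhibitor of primitive progenitors, was at 88.2 against 13.7 FPKM (2.60), MLLT3, a regulator of stem cell maintenance, at 14.7 against 2.91 FPKM, and NYNRIN at 4.74 against 0.762 FPKM (1.70). BAALC, a gene expressed in immature leukemia, went the other way, at 8.96 against 60.5 FPKM (-2.63), as did EMP1. Without CD34 the median of the stem cell list was 0.16, at percentile 99.8, and the mean of the list lay at percentile 96.5, inside the central 95%. Of 13 expressed leukemia surface antigens, 6 were higher and none lower, with a median of 0.65 at percentile 100 and of 0.49 without ESAM and CD34. They included CD33 and CD200, an immune inhibitory ligand, at 2.75 FPKM and listed at 0 in ESAM-Neg.

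Lists of other blood lineages were mixed. T and NK lymphocyte genes stood apart toward ESAM-Neg, with 2 higher, 5 lower and 9 neither of 16 expressed members and a median of -0.38 at percentile 0.05. The kinase LCK was at 2.89 against 19.98 FPKM (-2.43), the transcription factor TBX21 at 2.67 against 14.6 FPKM (-2.09) and the cytotoxic granule protein NKG7 at 102 against 345 FPKM (-1.75). The adhesion molecule NCAM1 at 72.8 against 31.1 FPKM and the T-cell receptor chain CD247 at 2.39 against 0.575 FPKM (1.11) went the other way. Of 5 expressed granulocyte genes, CSF3R, the G-CSF receptor, was at 20.4 against 1.38 FPKM (3.17) and CTSG, cathepsin G, at 33.4 against 6.83 FPKM (2.14), while the median of 0.17 lay at percentile 82.3. The granulocyte mean of 0.93 lay outside the central 95%, at percentile 98.5, and leaving out 1 member moved the median to between -0.09 and 1.15. Of 6 expressed monocyte genes, CD33 was higher and S100A9 lower. Their median was -0.09 at percentile 39.8, positive after equal scaling of the sums, and their mean was 0.02. Of 5 expressed erythroid genes, GATA1 was higher and CA2, carbonic anhydrase 2, was lower, at 181 against 978 FPKM (-2.43). The erythroid median was -0.07 at percentile 49.8, positive after equal scaling of the sums. Only 2 B lymphocyte and 4 dendritic or MHC class II genes were expressed, too few for a percentile. IGLL1, the surrogate light chain, was at 267 against 40.2 FPKM (2.70), CLEC9A, a dendritic cell receptor, at 9.01 against 0.898 FPKM (2.40), and BATF3, a dendritic cell transcription factor, at 12.9 against 31.4 FPKM (-1.22).

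**Figure D2:**
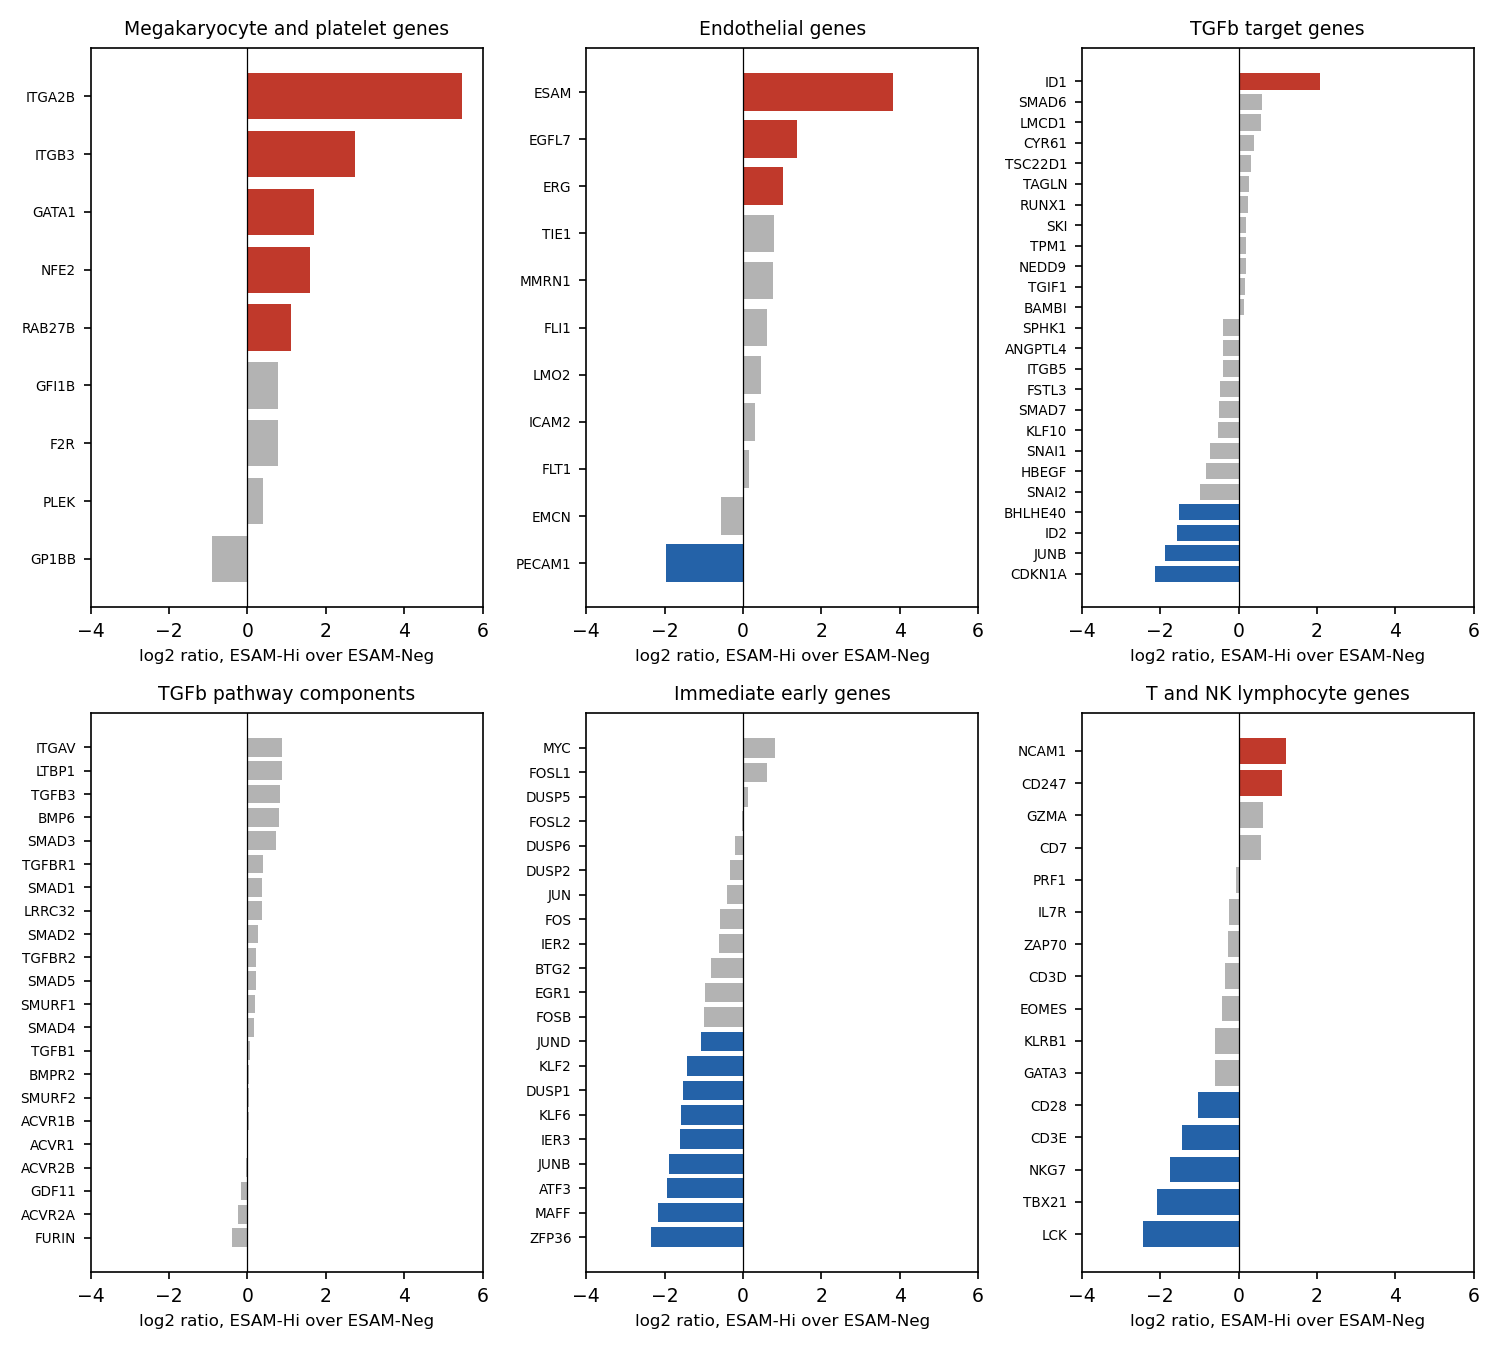
Bars give the log2 ratio of FPKM + 1, ESAM-Hi over ESAM-Neg, of each expressed member of 6 gene lists, red at 1 or above, blue at -1 or below and grey between. Megakaryocyte genes run up to 5.48 for ITGA2B, no TGFβ pathway component reaches 1 or -1, and immediate early genes run down to -2.35 for ZFP36.

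Immediate early genes, which are transcribed within minutes of a stimulus, formed the list furthest toward ESAM-Neg. Of 21 expressed members none was higher and 9 were lower in ESAM-Hi, and their median of -0.97 was below those of all random lists. ZFP36, which destabilises cytokine messengers, was at 15.5 against 83.0 FPKM (-2.35), the transcription factor MAFF at 1.82 against 11.7 FPKM (-2.17) and the stress-induced factor ATF3 at 7.86 against 33.0 FPKM (-1.94). KLF2, a quiescence factor, had a log2 ratio of -1.42. JUNB belonged both to this list and to the TGFβ targets. NFκB and TNF response genes included 7 lower members, with IL8, a neutrophil chemokine, at 1.12 against 15.6 FPKM (-2.97) and the cytokine LTB at 107 against 606 FPKM (-2.49). The chemokine CXCL3 at 3.39 against 0.597 FPKM (1.46) and IL1B at 88.5 against 39.7 FPKM (1.14) were higher, and the median of the 19 expressed members, -0.17, lay inside the central 95% at percentile 4.43. With a filter at 5 FPKM it lay outside, at percentile 0.10.

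Interferon response genes and MHC class I presentation genes stood apart toward ESAM-Neg by smaller amounts. Of 30 expressed interferon response genes none was higher and 5 were lower, with a median of -0.26 at percentile 0.02. ISG15, a ubiquitin-like modifier, was at 28.1 against 81.5 FPKM (-1.50), IFI35 at 9.06 against 25.4 FPKM (-1.39) and the transcription factor IRF1 at 11.7 against 29.9 FPKM (-1.29). None of 14 MHC class I genes was past the rule. The immunoproteasome subunits PSMB10 and PSMB9 had log2 ratios of -0.87 and -0.54 and the non-classical class I gene HLA-E had -0.60, with a list median of -0.33 at percentile 0.07. By their means both lists lay inside the central 95%, at percentiles 4.46 and 10.3.

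Most stress and protein folding genes were below 0, in general by small amounts. All 13 expressed heat shock genes and 15 of 22 unfolded protein and ATF4 response genes lay on that side. None of 13 expressed heat shock genes was past the rule, and their median was -0.27 at percentile 1.79, which moved inside the central 95% (3.47) when random lists were matched on the value in ESAM-Neg. The chaperone regulators BAG3 and DNAJA1 had log2 ratios of -0.56 and -0.45 and the inducible chaperone HSPA1B had -0.44. Of 22 unfolded protein and ATF4 response genes 3 were lower, ATF3 and DDIT3, a mediator of stress-induced death, at 3.90 against 10.04 FPKM (-1.17) among them, with a median of -0.15 at percentile 11.7.

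Cell cycle genes differed by small amounts in opposite directions. G1/S and DNA replication genes lay toward ESAM-Neg, with a median of -0.21 over 26 genes at percentile 1.80, led by the transcription factor E2F1 (-0.71), the ribonucleotide reductase subunit RRM2 (-0.51) and the licensing factor CDT1 (-0.42). G2/M genes lay toward ESAM-Hi, with a median of 0.09 over 28 genes at percentile 99.97, led by the mitotic kinase TTK (0.47), TOP2A (0.47), the topoisomerase of dividing cells, and the spindle protein DLGAP5 (0.35). No gene of either list was past the size rule, and both calls ended with the list mean, at percentiles 11.3 and 94.3. Of 17 cell cycle inhibitors and quiescence genes 3 were lower, CDKN1A and KLF2 among them, with a median of 0.02 at percentile 55.7 and a mean of -0.27. Of 30 MYC targets only CCND2, cyclin D2, was past the rule, at 5.28 against 0.149 FPKM (2.45), and the median of -0.13, positive after equal scaling of the sums, lay at percentile 25.4.

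Glycolysis and nuclear oxidative phosphorylation genes both lay toward ESAM-Neg without any gene past the rule. The glycolysis median was -0.33 over 20 genes at percentile 0.02, with TPI1 at 282 against 413 FPKM (-0.55), ALDOA at 772 against 1092 FPKM (-0.50) and the glucose transporter SLC2A3 at 19.3 against 27.3 FPKM (-0.48). The oxidative phosphorylation median was -0.24 over 34 genes at percentile 0.40, with CYC1 (-0.49), NDUFS7 (-0.42) and ATP5D (-0.40) in the lead. Of 16 hypoxia response genes only NDRG1, a stress-responsive gene, was past the rule, at 23.1 against 87.0 FPKM (-1.87), with FAM162A and PFKFB4 at -0.45 and -0.42 and a median of -0.20 at percentile 1.22. By list means these 3 lists lay inside the central 95%, at percentiles 6.62, 16.4 and 14.7. Cholesterol synthesis genes (20 expressed, median -0.19, percentile 9.05) and fatty acid synthesis genes (12 expressed, median -0.18, percentile 13.7) did not stand apart and held no gene past the rule. None of the 13 genes of the mitochondrial genome list is in the files.

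The list of ribosomal protein genes, with 38 expressed members and none past the rule, had a median of -0.05. That median turned positive after equal scaling of the sums or of the 75th percentiles. It lay at percentile 97.9 because genes matched on their high expression had a lower median of -0.14, and at percentile 28.0 among unmatched lists. RPS3, RPS18 and RPLP0 had log2 ratios of 0.29, 0.16 and 0.11. RPS28, which was past the rule with a log2 ratio of 3.78, is not in this list. It was at 42.3 FPKM in ESAM-Hi and 2.16 FPKM in ESAM-Neg, far below RPS3 at 1307 and 1066 FPKM. The reason for these low values was not tested. The 28 expressed housekeeping genes had a median of -0.09, positive after equal scaling of the sums, at percentile 61.5 with none past the rule.

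Adhesion and homing genes lay toward ESAM-Hi in several lists. Of 15 expressed matrix and integrin genes, ITGA2B and ITGB3 were higher and ITGB7 (0.468 against 9.94 FPKM, -2.90) and ITGA3 (-1.36) lower, with ITGAV at 0.88 and a median of 0.39 at percentile 99.99. Of 6 expressed epithelial and tight junction genes JUP, plakoglobin, was higher, at 31.0 against 14.03 FPKM (1.09), with CTNND1 at 0.60 and a median of 0.41 at percentile 99.7. Of 12 chemokine receptor and homing genes 2 were higher, CCR2 (1.10 against 0.0442 FPKM, 1.01) among them, CCR1 was at 0.75 and CXCR3 was lower, with a median of 0.45 at percentile 99.99. By list means all 3 lists lay inside the central 95%, at percentiles 97.4, 97.0 and 70.1. Of 14 EMT genes, the repressor ZEB2 (10.2 against 0.890 FPKM, 2.57) and N-cadherin, CDH2 (20.1 against 6.53 FPKM, 1.49), were higher and the matrix protease MMP9 was lower (0.0752 against 2.08 FPKM, -1.52), with a median of 0.03 at percentile 57.7. With a filter at 5 FPKM the EMT median was 0.46, outside the central 95% at percentile 99.98. Among actin and YAP response genes only CNN2, calponin 2, was past the rule (9.99 against 24.6 FPKM, -1.22). The 21 members had a median of -0.01 at percentile 85.3, positive under 3 of 3 scalings tried.

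Signalling lists held single genes with large ratios. Of 16 expressed JAK-STAT targets, ID1 and the feedback inhibitor SOCS2 (1.65) were higher, BCL6, a transcriptional repressor, was lower (0.417 against 8.81 FPKM, -2.79), as was the receptor chain IL2RB (7.38 against 28.4 FPKM, -1.81), and STAT5A was at 0.85. The median of 0.25 lay at percentile 99.9, but the mean was -0.01, at percentile 54.3. In the list around FGFR1, which is part of a fusion gene in KG1 cells, the receptor tyrosine kinase inhibitors SPRY2 (12.7 against 4.55 FPKM) and SPRY1 (24.4 against 9.79 FPKM, 1.23) were higher and ETV5 was at 0.56. The median over 9 genes was 0.33 at percentile 99.4, and the call ended without a filter on low values (66.3), with a pseudocount of 5 (88.2) and with the list mean (95.8). Of 9 Notch and Wnt response genes only the ligand JAG2 was past the rule (0.674 against 3.30 FPKM, -1.36), with a median of -0.02 at percentile 31.3 that turned positive after equal scaling of the sums or of the 75th percentiles.

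Survival and efflux genes did not stand apart. Of 22 expressed apoptosis regulators the pro-apoptotic BMF (1.24 against 6.89 FPKM, -1.82) and BBC3 (1.80 against 4.61 FPKM) were lower, with a median of -0.16 at percentile 2.63. That percentile crossed the limit with equal sums (2.26), equal 75th percentiles (2.28) and a filter at 5 FPKM (1.26). Of 17 p53 targets CDKN1A and BBC3 were lower, with a median of -0.06, positive after equal scaling of the sums, at percentile 21.0. Of 9 drug efflux transporters the lipid exporter ABCA1 was lower (log2 ratio -1.72), with a median of 0.23 at percentile 94.1. Of 12 histone genes HIST1H1C was lower (3.51 against 8.07 FPKM, -1.01), with a median of -0.23 at percentile 5.

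In all, 39 lists had at least 5 expressed members, of which 11 stood apart toward higher and 10 toward lower percentiles and 18 did not. Chance alone puts 1.95 of 39 independent lists outside the central 95%. Of the 21 that stood apart, 5 did so under every alternative run for them: endothelial genes, leukemia surface antigens, megakaryocyte genes, immediate early genes, and T and NK lymphocyte genes. Equal scaling of the sums moved the median of all expressed genes from -0.01 to 0.11, so small list medians are positions relative to other genes and not absolute levels.

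**Figure D3:**
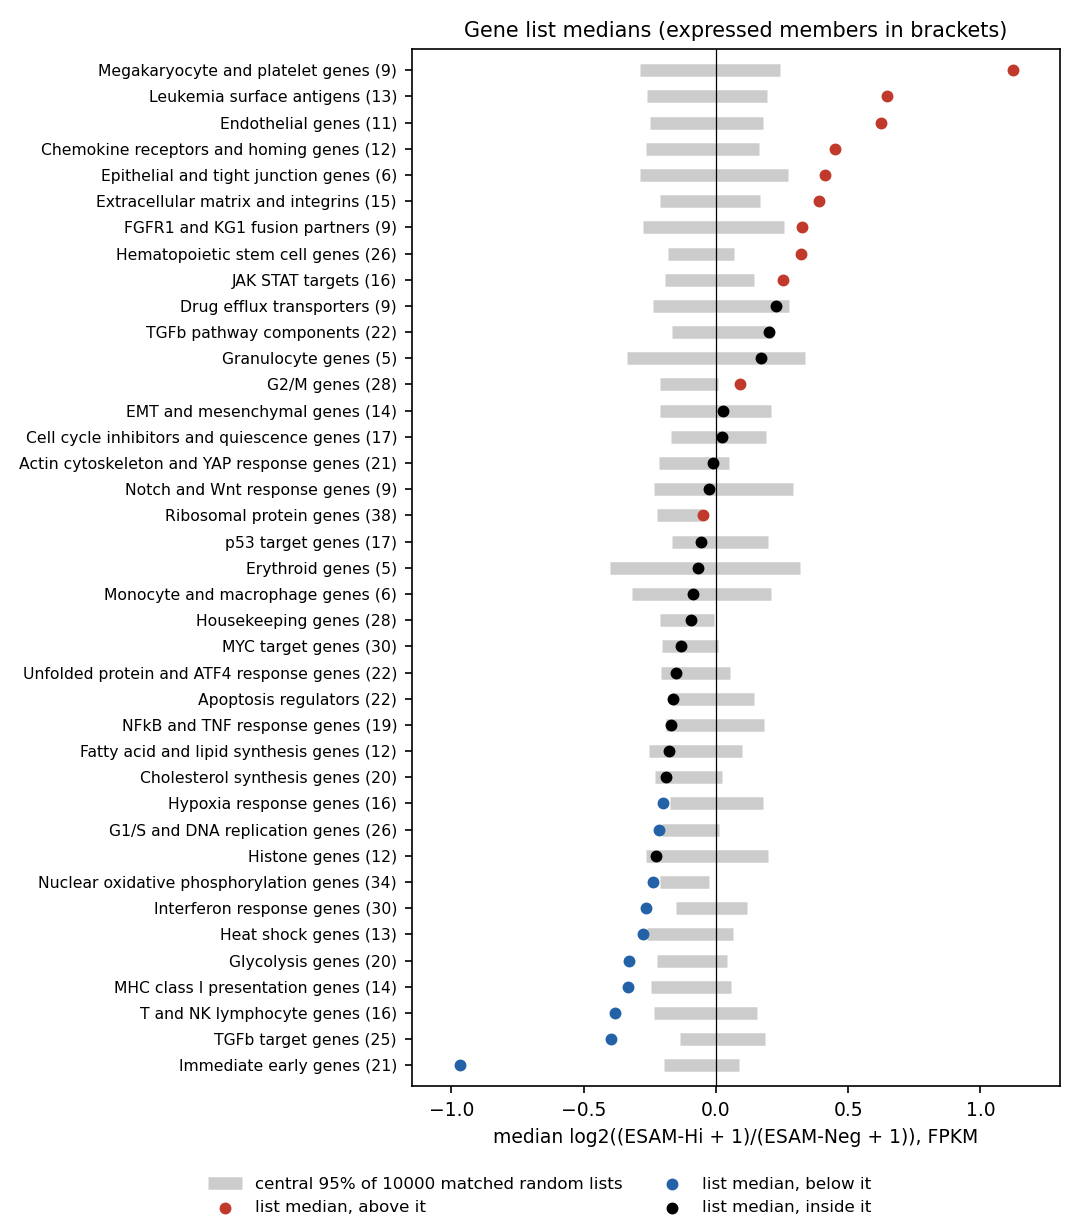
Points give the median log2 ratio of FPKM + 1, ESAM-Hi over ESAM-Neg, of the expressed members of 39 gene lists (number in brackets), and grey bars the central 95% of 10000 random lists matched on mean expression. The 11 medians above their bar are red, the 10 below are blue and the 18 inside are black, from 1.12 for megakaryocyte genes to -0.97 for immediate early genes; the medians of the monocyte, erythroid, MYC, ribosomal, p53, Notch, actin and housekeeping lists turn positive under at least 1 other scaling.

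Neighbouring genes were shifted together along stretches of 2 chromosomes, which was seen only after the genes past the size rule had been listed. On chromosome 11, 201 consecutive genes of at least 5 FPKM, from CHKA to ACAD8, the last one placed on the chromosome, were higher in ESAM-Hi by a median centred log2 ratio of 0.33 (1.25-fold), with 175 of them (87.1%) above the median of all genes. The stretch holds ESAM and ZBTB16 among others. FXYD2 and, named after their values were seen, CD3E, CARD17, CASP1 and CARD16 lie in it too and were lower by the size rule. The 10 genes before it had a median of -0.02. On chromosome X, 37 consecutive genes from CETN2 to VBP1 were lower in ESAM-Hi by a median of -0.80, which is 1.74-fold higher in ESAM-Neg. Of these 35 (94.6%) were below the median of all genes, with HCFC1 and MPP1 as the exceptions, and 11 were past the size rule. They encode unrelated proteins. Examples chosen after their values were seen, as were the other genes named along X, and lying beyond the median of the stretch are the acetyltransferase NAA10 at 114 against 255 FPKM (-1.16) and the signalling kinase IRAK1 at 91.5 against 203 FPKM (-1.14). The 10 genes before the stretch had a median of 0.14, and of the 2 placed genes after it CLIC2 was higher in ESAM-Hi, at 5.36 against 0.341 FPKM (2.24), and TMLHE lower, at 9.18 against 13.9 FPKM (-0.55), so the end of the stretch is not sharp.

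The run scores were 22 on chromosome 11 and 20.3 on X, against a highest score of 5.55 in 1000 shuffled gene orders. Lower scores, also above 5.55, belonged to 15 genes of a zinc finger cluster on chromosome 19 from ZNF506 to ZNF254 (median 0.71, score 6.75, 10 genes before 0.01 and after -0.13) and to 43 genes on chromosome 22 from APOL2 to APOBEC3H (median -0.21, score 6.05). The genes beside the stretch on 22 were nearly as low, with medians of -0.16 for 10 before it and -0.11 for 10 after it. Shuffling treats neighbours as unrelated, which members of gene clusters are not. Leaving out the stretches on 11 and X left 307 higher and 272 lower genes by the size rule.

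**Figure D4:**
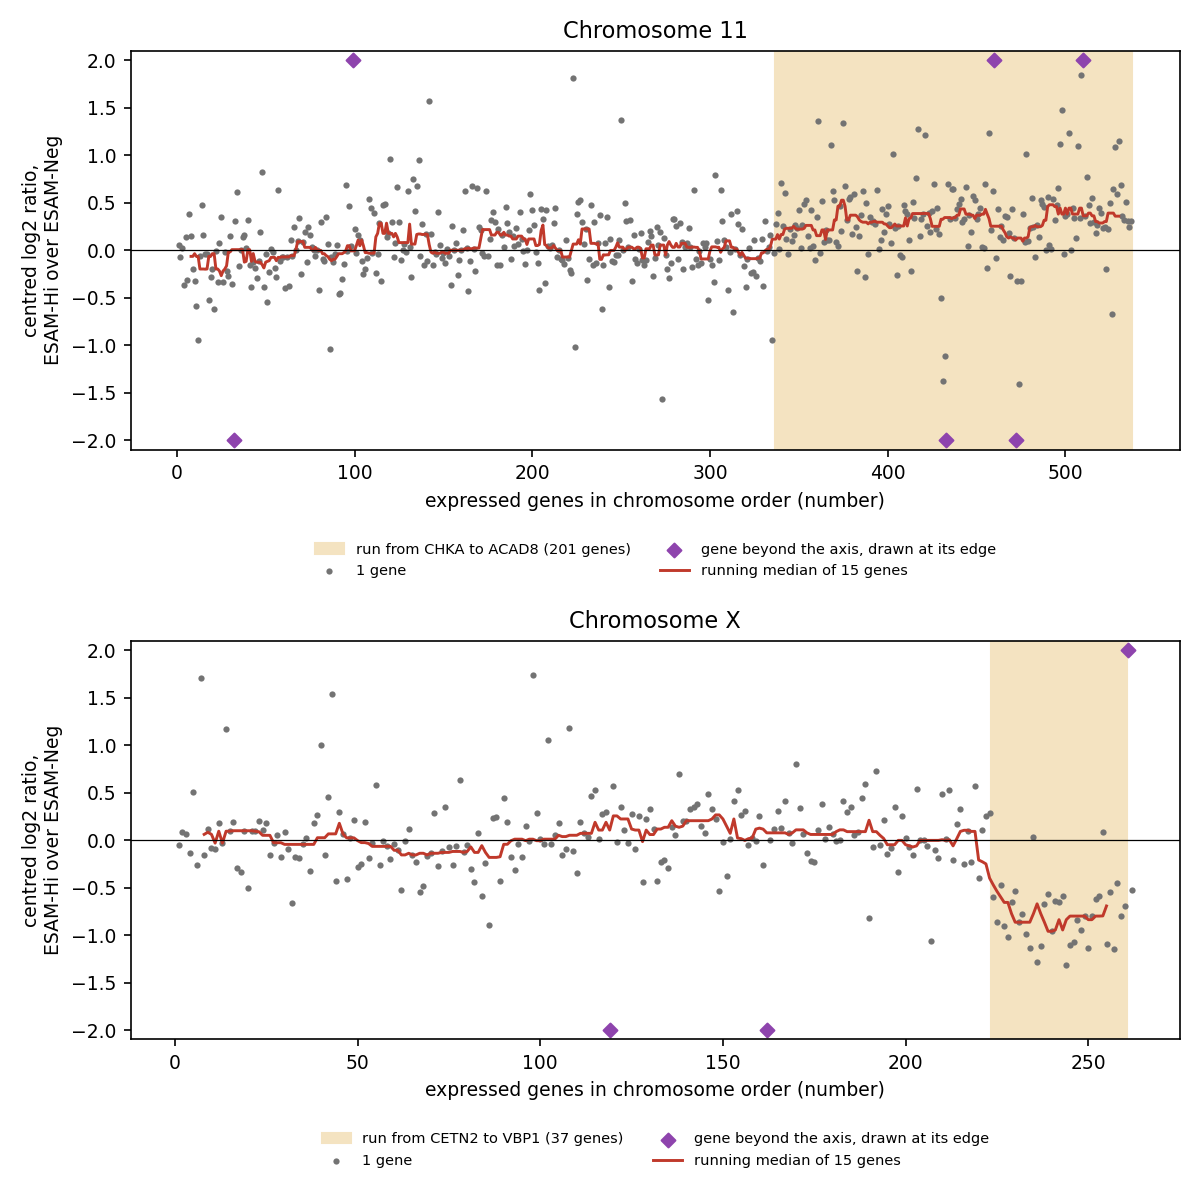
Each point is 1 gene of at least 5 FPKM on chromosome 11 or X in chromosome order, with its log2 ratio of FPKM + 1 (ESAM-Hi over ESAM-Neg, centred on the median of all placed genes) on the vertical axis and a running median of 15 genes as the red line. In the shaded stretches the 201 genes on chromosome 11 have a median of 0.33 and the 37 genes on X one of -0.80; diamonds are genes beyond the axis, drawn at its edge.

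Counting error of the fragments alone put 5.71 genes past the size rule on average in 100 draws. Seen were 548 among the 10315 expressed genes with a known transcript length, 442 of them of at least 500 bases. The fragment numbers behind the draws were set from genes of at least 1000 bases. For genes under 500 bases the draws may thus understate the counting error. Genes under 500 bases passed it more often, 42.7% of 248 against 4.39% of longer ones, so values of short genes such as SCARNA1 and SCARNA21 are the least certain. Ratios also tended to be higher for longer transcripts (Spearman rho 0.21 across genes). Matching random lists on length ended the call of hypoxia genes (percentile 8.17) and of no other list.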

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

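The alternatives matched on transcript length, without short RNA genes, without sort markers, without single list members and without the stretches on chromosomes 11 and X were chosen after seeing the data. Over all settings, no single gene past the size rule changed direction and no list that stood apart moved to the other side of the random lists, although the ribosomal median turned positive with equal sums (0.08) and equal 75th percentiles (0.01) and the JAK-STAT mean was below 0 (-0.01): of 590 settings of single genes 560 kept their side of the rule, 28 fell short of it and 2 newly passed it, and of 467 settings of lists 426 kept their call, 27 lost one and 14 gained one. The ESAM and CD34 ratios kept their side of the rule under each. The cause of the changes below was not tested, except that the counts follow from their own construction. The highest value per symbol was not run, since no symbol repeats. Leaving out a replicate was not possible and no paired analysis was possible because each group has 1 library. The approximate depth of 11.4 and 9.72 fragments per kilobase at 1 FPKM limits genes near that level.

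A pseudocount of 5 gave 144 higher and 152 lower genes, one of 0.1 gave 468 and 440, a 1.5-fold limit 787 and 759 and a 4-fold limit 97 and 78. Pearson r was 0.855 among genes of at least 5 FPKM.

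With the mean in place of the median, percentiles moved inside the central 95% for TGFβ targets (2.55), epithelial (97.0), matrix and integrin (97.4), stem cell (96.5), MHC class I (10.3), interferon (4.46), heat shock (6.37), G1/S (11.3), G2/M (94.3), ribosomal (95.3), oxidative phosphorylation (16.4), glycolysis (6.62), hypoxia (14.7), chemokine (70.1), JAK-STAT (54.3) and FGFR1 genes (95.8), and outside for granulocyte (98.5) and NFκB genes (0.82). Matching on the value in ESAM-Neg ended the calls of heat shock (3.47), G1/S (5.80) and oxidative phosphorylation genes (2.68) and set histone genes apart (1.38). Unmatched lists ended those of G2/M (94.0) and ribosomal genes (28.0) and set TGFβ components (99.6) and cholesterol genes (2.09) apart. Without a filter on low values TGFβ targets (6.87), ribosomal (97.2), chemokine (93.6) and FGFR1 genes (66.3) lost their calls and actin genes gained one (99.9). A filter at 5 FPKM set EMT (99.98), NFκB (0.10) and apoptosis genes (1.26) apart. A pseudocount of 5 ended the call of FGFR1 genes (88.2) and set TGFβ components apart (98.0). Apoptosis genes also stood apart with equal sums (2.26), equal 75th percentiles (2.28) and without the stretches on 11 and X (0.77), as did actin genes in the last setting (98.9). Matching on length, which also left out members without a known length, ended the call of hypoxia genes (8.17).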

Other observations

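The tests of handling genes, of shuffled gene order and of length and expression along chromosome X were chosen only after the results they bear on had been seen. The predictions for the other tests were written before their values were looked at. HPGDS, GATA2 and the handling genes were chosen after their values were seen. So were the members named below from the 16 other mast cell and basophil genes.

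A mast cell and basophil group of genes lay toward ESAM-Hi. HPGDS, the prostaglandin D synthase of these cells, was at 86.2 FPKM in ESAM-Hi and 10.96 FPKM in ESAM-Neg (log2 ratio 2.87), and with IL1RL1 and GATA2, a transcription factor of both stem cells and mast cells at 89.7 against 27.5 FPKM (1.67), it led to a look at 16 other genes of that lineage. Of these 8 were expressed, with a median of 1.11, above those of all random lists (percentile 100). Above that median lay carboxypeptidase CPA3 at 167 against 73.9 FPKM (1.17) and the histamine-forming enzyme HDC at 6.24 against 2.05 FPKM (1.25). So did the tryptase TPSB2 at 2.67 against 0.0981 FPKM (1.74) and PTGS1 at 3.57 against 0.907 FPKM (1.26). PRG2 went the other way, at 5.55 against 7.97 FPKM (-0.45), and KIT, MITF and CLC were near or at 0 in both libraries. GATA2 is also in the stem cell list and PRG2 in the granulocyte list. A candidate explanation is that a mast cell or basophil program is more active in the ESAM-Hi fraction, since the other genes of that lineage lay at percentile 100. With 1 library per fraction, a difference between cultures or sorts stays open.

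The megakaryocyte genes at 1.12 invite the question whether platelets or megakaryocytes were among the sorted cells. PF4 and PPBP, among the most abundant transcripts of those cells, were at 0% of the level of ITGA2B. This argues against such cells as far as a value listed at 0 means no expression, which FPKM without counts cannot show. The sorted cells are also a cultured line gated on CD34. Transcript length was argued against by random lists matched on it (percentile 100). A program of that lineage shared by the cells themselves is a hypothesis that no value here tests further.

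The medians of immediate early genes and of TGFβ targets lay toward ESAM-Neg, and both stayed below all random lists matched on length (percentile 0 for each). For the TGFβ targets 12 of 25 ratios were above 0, and the call was lost without a filter on low values (6.87) and with the list mean (2.55). Sorting and handling may induce such genes. A set of 5 genes often read as signs of handling, FOS, FOSB, EGR1, HSPA1A and HSPA1B, had a median log2 ratio of -0.59. FOS, FOSB and EGR1 belong to the immediate early list itself, the median is the value of FOS, and HSPA1A was below 1 FPKM in both libraries. The value thus restates the observation, and whether handling played a part was left untested. The TGFβ targets without JUNB, the member shared with the immediate early list, lay at percentile 2.33, with a median of -0.13. Leaving out SMAD7 instead gave the same median, so this value says nothing about JUNB or about shared members, and the question was left untested.

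The scores of the stretches on chromosomes 11 and X were above the highest score in shuffled orders, 5.55. Shuffling treats neighbours as unrelated, the search was devised after neighbours had been noticed, and stretches on 19 and 22 passed the same limit. The comparison thus cannot exclude a chance likeness of neighbours in these 2 libraries. Transcript length and expression level did not account for the stretch on X, whose median was -0.73 after centring within bins of both. A difference in copy number between the fractions may shift all genes of a stretch alike, whatever they encode. Genes of 1 to 5 FPKM, which took no part in finding the stretches, were used to test this: on X 6 of 6 (100%) lay on the side of the stretch, fewer than the 8 genes asked for in advance, and on chromosome 11 30 of 41 (73.2%) did, just under the 75% asked for, against 38.5% of such genes elsewhere on that chromosome. Both results leave the question open, regional regulation of transcription would look the same, and no DNA was measured.

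As to technical sources of the genes past the size rule, draws of counting error gave 5.71 of them on average. These draws may understate the error of genes under 500 bases, since their fragment numbers were set from genes of at least 1000 bases. Genes of at least 500 bases made up 80.7% of those with a known length, so short gene models were not the main source.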
